A study of Mus musculus with 8 samples.

How the data were processed

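Gene expression was measured by RNA-seq in 8 libraries of AML-12 cells, 4 with the control vector and 4 overexpressing Gm47544. Per the labels' protocols, RNA was extracted with Trizol and made into libraries with an NEBNext Ultra kit. The authors deposited 1 table of raw counts per gene symbol, with 21983 symbols and 8 libraries, and all values were whole numbers with no normalization. Per the submitters' processing notes, the tools were FastQC, STAR and HTSeq with the mm10 build. Their versions, the annotation and the strand setting of the counting are not given in the sources used here. Groups and replicate numbers were taken from the sample titles.

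Symbols were matched to GENCODE M21 on GRCm38, the assembly that mm10 names, and 21926 of 21983 matched, of which 99.7% were annotated as protein coding. Gm47544 was not analysed here, so the check of the labels by the overexpressed gene could not be made. The counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with a minimum count of 10, which left 11520 of the 16281 genes with at least 1 count. Libraries were scaled by trimmed-mean factors, and the groups were compared with the two-sided quasi-likelihood test with group as the only term and Benjamini-Hochberg adjustment, called at 0.05. CPM values use the scaled library sizes. The common biological coefficient of variation was 0.15. Standard errors were the log2 fold change divided by the square root of the test's F. A gene with no counts in a group was set against a floor of 3 counts over that group, or 0.0509 CPM in controls and 0.0548 CPM in overexpression libraries. Ratios of low counts carry exact 95% binomial intervals, and intervals and floors cover counting error only.

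Gene lists of 21 pathways and 5 sets of cell type markers were fixed before the data were examined. Lists with at least 5 tested members, 22 in all, were tested with camera in limma 3.58.1 at a preset correlation of 0.01, adjusted over the lists, and again with an estimated correlation and with fry. The transferrin gene was listed under a symbol that matched no row, and 2 matrix genes were each listed under 2 symbols of which 1 matched. Named genes followed a rule fixed at the same time: 10 lipoprotein genes, the 8 largest changes in each direction among called genes with at least 1 CPM on average, no overlap of the groups and an established symbol, up to 4 called members with the smallest p of each list that passed and up to 2 of each other list, and the nearest tested neighbours of Gm47544. A few members outside the rule were named after their values were seen, as stated beside them. Some genes that the rule names are not reported here.

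Library pairs of the same group were compared by a chi-square per gene, which lay between 2.5 and 114, so no pair matched within counting noise. The test was run on simulated data with the real means and library sizes and 1 spread per gene for all libraries. Genes were drawn independently, with 50 changed at each fold. That simulation held no shared trends and far fewer changed genes than the real data, so its rates may not carry over. In the simulation of control against overexpression on 11443 genes it recovered 46% of genes changed 1.5-fold, 94% changed 2-fold, 100% changed 4-fold and 100% changed 8-fold, with 14 false calls among 184. Alternatives were other scalings, filters, a replicate block, leaving out each library, DESeq2 1.42.0 and limma-voom with quality weights. Corrections for trends on gene length and on GC content (lowess, span 0.3), alone and 1 after the other, and centring within chromosomes were added after seeing the data. In the sensitivity results a list's direction was read from the sign of its median; this replaced the direction of the list test after the results had been seen, and it changes which lists count as reversed. The direction of the list test itself also turned under some alternatives for the cholangiocyte, ubiquitin and hepatocyte identity lists. Figures were drawn with matplotlib 3.10.9.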

Results

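RNA-seq gene counts were analysed from AML-12, an established line of mouse hepatocytes. The series held 4 libraries of cells with the pLKO.1 vector, a lentiviral backbone used as the control. The other 4 libraries were of cells overexpressing Gm47544, a long non-coding RNA gene, and their titles name no vector. The series title ties Gm47544 to the ubiquitination of APOC3, a protein of triglyceride-rich lipoproteins that slows their clearance, so the comparison of both groups asked which transcripts differed when Gm47544 was overexpressed. Library totals were 12256376, 18965662, 15858645 and 14270022 counts in control libraries 1 to 4 and 11119919, 17338310, 11016907 and 12881693 in overexpression libraries 1 to 4. The groups did not differ detectably in total counts (two-sided exact permutation test, p = 0.343). The labels did not say whether the libraries of a group came from separate cultures, so the p-values measure the spread between these libraries, which may be technical.

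Expression differed between the groups across most of the transcriptome. Of 11520 genes tested, 7417 (64.4%) changed at an adjusted p below 0.05 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 3720 higher and 3697 lower in the overexpression libraries. At least 2-fold changes were found for 1327 higher and 1039 lower genes, and at least 4-fold changes for 290 higher and 129 lower genes. The 4 control and the 4 overexpression values did not overlap for 6447 tested genes (56%), against 2.86% by chance. Scaling by library totals alone shifted the median log2 fold change of all tested genes by 0.128, and the changes below are relative to the trimmed-mean scaling, under which that median was 0.000406. The balance of calls also depended on the scaling: 58.4% of 7375 were higher with library totals alone, against 50.2% with the trimmed-mean scaling. The first principal component separated the groups and held 82.5% of the variance. Control library 3 lay at -22.2 on it, the other controls between -60.7 and -50 and the overexpression libraries between 43.5 and 50.4. Without control library 3, 9001 genes changed.

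**Figure D1:**
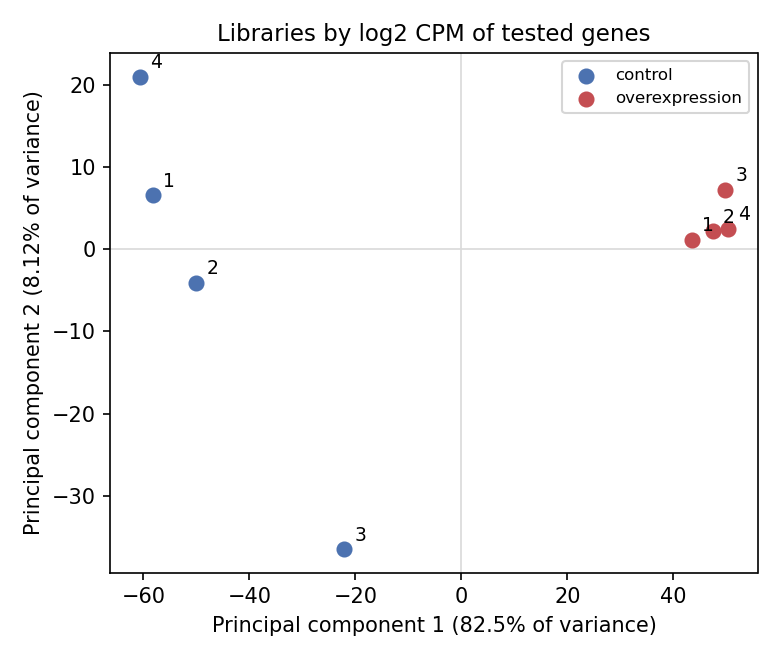
Position of each library on principal components 1 and 2 of log2 CPM over the tested genes (axes in component units, with the percent of variance; each point is a library, labelled with its replicate number). The overexpression libraries lie between 43.5 and 50.4 on component 1, and control library 3 lies at -22.2, apart from the other controls.

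Apoc3 transcripts were near the limit of detection in both groups, while Apoa5, from the same gene cluster, had far more reads in the overexpression libraries. Apoc3 (chromosome 9, 46232933 to 46235636, GRCm38, minus strand) had 13 counts over the 4 control libraries and 13 over the 4 overexpression libraries, or 0.211 ± 0.13 and 0.235 ± 0.0901 CPM (SD, n = 4). It did not pass the count filter, and without the filter its log2 fold change was 0.089 (SE 0.68, adjusted p = 0.928 in edgeR's quasi-likelihood test), so no difference was detectable at this depth. Apoa5, an apolipoprotein that promotes the hydrolysis of plasma triglycerides, had 14 control and 196 overexpression counts, 0.236 ± 0.145 against 3.66 ± 0.671 CPM (SD, n = 4), a log2 fold change of 3.89 (SE 0.36, adjusted p = 2.97e-06 in edgeR's quasi-likelihood test). Gm47544 itself was not analysed here. The annotation places it on chromosome 9 from 46270035 to 46271365 on the minus strand, inside Apoa5 (46268633 to 46271919, plus strand). Its exon 1 (46271018 to 46271365) and exon 2 (46270035 to 46270210) hold 524 bases, and all 524 lie within Apoa5 exons on the opposite strand. Whether the counting used strand is not given in the sources used here, so reads of Gm47544 and of Apoa5 could not be told apart and the Apoa5 value is uncertain. Apoa1, the main apolipoprotein of high-density lipoprotein, had 43 and 59 counts (log2 fold change 0.49, SE 0.48), which passed only with the trend on gene length removed, and Apoa4 had 0 and 3. Of the nearest tested genes, Zpr1 and Sik3 did not pass (log2 fold changes -0.079 and 0.26), although Zpr1 was lower with chromosome centring and Sik3 was called in some alternatives (edgeR, adjusted p from 6.1e-05 to 0.952), and Bud13 had -0.35, a call lost in 8 of 19 alternatives (edgeR, adjusted p = 0.0424, and 0.00207 to 0.159 over the alternatives).

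**Figure D2:**
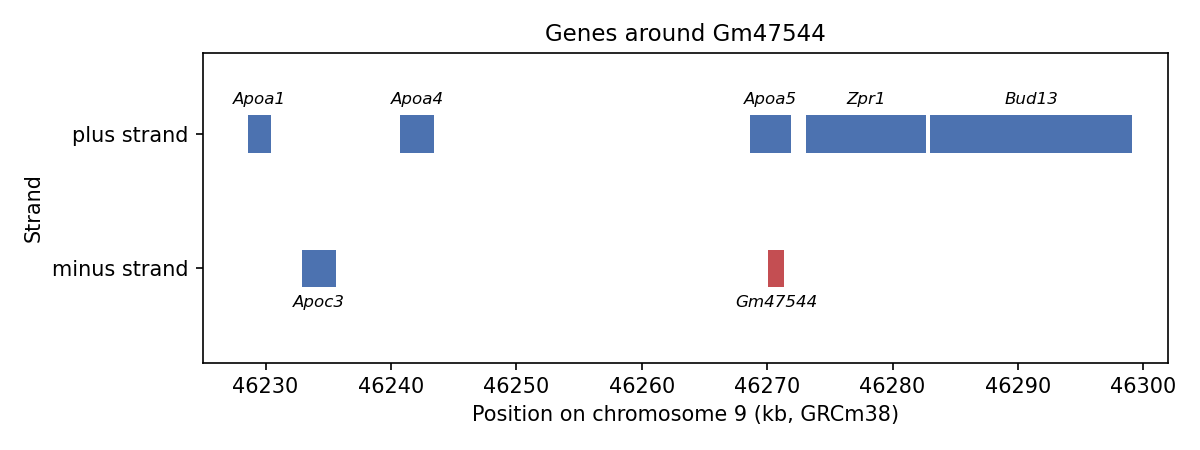
Genes around Gm47544 on chromosome 9 (horizontal axis, position in kb, GRCm38; vertical axis, strand; each bar spans a gene from start to end). Gm47544 (46270035 to 46271365) lies on the minus strand within the span of Apoa5 on the plus strand.

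The lipoprotein assembly genes Mttp and Apob rose, while Lpl had almost no overexpression counts. Mttp, which loads lipid onto apolipoprotein B, rose from 5.32 ± 1.58 to 13.1 ± 0.394 CPM (SD, n = 4; log2 fold change 1.29, SE 0.19, adjusted p = 7.73e-05 in edgeR's quasi-likelihood test). Apob, the structural protein of very-low-density lipoprotein, was higher at 244 ± 15.1 against 145 ± 48.7 CPM (SD, n = 4; log2 fold change 0.76, SE 0.18). The Apob log2 fold change was 0.14 once the trend on gene length was removed from each library (edgeR, adjusted p = 0.323, the highest of 19 alternatives, the lowest being 6.59e-10), and Apob was at 216 CPM in control library 3 and between 108 and 128 CPM in the other controls. Apoe was at 4.93 ± 0.333 and 5.16 ± 1.27 CPM, a difference within the replicate spread. Lpl, which hydrolyses lipoprotein triglyceride, had 44 control counts and 1 overexpression count, a ratio of 40.8 at equal depth (95% exact interval 6.95 to 1648, counting error only). Across the fixed list of triglyceride-rich lipoprotein genes, 6 of 16 tested members rose and 6 fell, the median log2 fold change was -0.016, also with Scarb1 set at its bound, and 0.12 with scaling by library totals alone, and the list did not pass the list test (camera, adjusted p = 0.547).

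**Figure D3:**
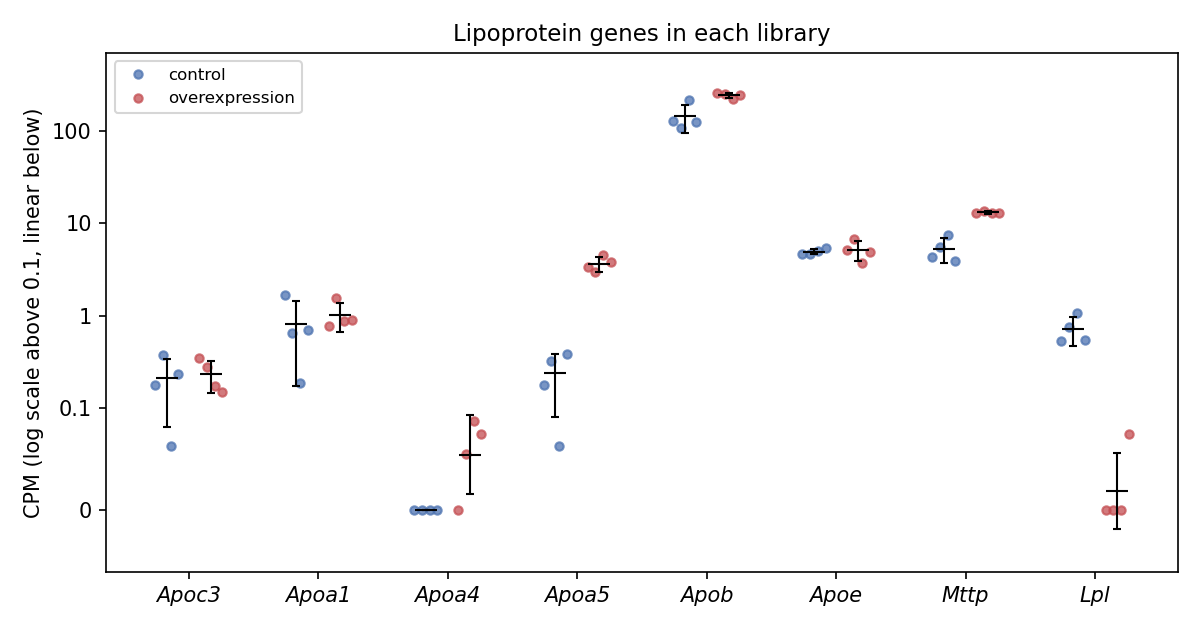
CPM of 8 fixed lipoprotein genes in each library (vertical axis logarithmic above 0.1 and linear below; coloured points are libraries, black bars the mean ± SD of 4). Apoa5 and Mttp lie higher and Lpl lower in the overexpression libraries, and Apoc3 lies below 1 CPM in all 8.

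The largest decreases included genes with no overexpression counts at all. Scarb1, the receptor for high-density lipoprotein, had 237 control counts and 0 overexpression counts, at least 75.9-fold lower against a floor of 3 counts over the group. Evc and Evc2, adjacent genes of a ciliary complex, had 268 and 212 control counts and 0 overexpression counts, at least 81.9-fold and 64.5-fold lower, and Atp9a, a phospholipid flippase, was at least 39.9-fold lower. Abca1, which exports cellular cholesterol, fell from 16.6 ± 5.08 to 0.102 ± 0.125 CPM (SD, n = 4; log2 fold change -7.37, SE 0.45, adjusted p = 1.69e-07 in edgeR's quasi-likelihood test). Gpnmb had 183 control counts against 1, a ratio of 170 (95% exact interval 30.1 to 6742), and Dync2li1 153 against 1, a ratio of 142 (25.1 to 5643). Fam57b fell by 6.07 on the log2 scale. Fam57b overlaps Aldoa in the annotation, so its counts are uncertain. Among the highest, Ifit1bl2, a relative of the interferon-induced Ifit1, rose from 1.2 ± 0.624 to 147.9 ± 29.4 CPM (SD, n = 4; log2 fold change 6.98, SE 0.28). Speer4f1, Ces3a, Slc22a8 and Fmod had 1, 3, 2 and 3 control counts against 226, 164, 111 and 154, ratios of 244 (43.3 to 9664), 58.9 (19.8 to 289), 59.8 (16.2 to 500.1) and 55.3 (18.6 to 271). Cyp4a32, Ugt2b37 and Aplnr rose by log2 fold changes of 5.96, 5.33 and 5.21. Ifit1bl2, Speer4f1, Cyp4a32, Ces3a and Ugt2b37 belong to families of similar sequence, so their reads may be shared with relatives.

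Transcripts for the respiratory chain, the cytosolic ribosome and the proteasome were lower as groups. Nuclear genes of oxidative phosphorylation fell for 37 of 40 tested members and rose for 1 (median log2 fold change -1.03; camera, adjusted p = 6.03e-13, and adjusted p = 0.283 with an estimated correlation). Uqcrq, a subunit of complex III, fell from 531 ± 151 to 133 ± 7 CPM and Cox6c, a subunit of complex IV, from 420 ± 105 to 133 ± 4.06 CPM (SD, n = 4). Ribosomal protein genes fell for 40 of 44 members and rose for 2 (median -1.02; camera, adjusted p = 1.8e-10, and adjusted p = 0.324 with an estimated correlation), among them Rplp1 and Rps19 with log2 fold changes of -1.54 and -1.62 (-0.46 and -1.65 with the trend on gene length removed). Ribosomal genes have many processed pseudogenes, and members with few counts may have lost reads to them. Proteasome genes fell for 27 of 31 members and rose for 0 (median -0.65; camera, adjusted p = 8.66e-06, and adjusted p = 0.283 with an estimated correlation), with Psmb7 at a log2 fold change of -1.49 and Psmb3 at -1.28. The 3 medians were -0.54, -0.50 and -0.31 once the trend on gene length was removed, and the calls held at the preset correlation. The estimated correlations were far higher, at 0.524 for oxidative phosphorylation, 0.477 for the ribosome and 0.197 for the proteasome. With them these 3 lists did not pass even without the length correction, so the small p-values depend on the preset. Over 16 alternatives with camera the adjusted p of the list test ran from 5.65e-16, 1.55e-12 and 9.62e-07 up to the values with an estimated correlation. The share of counts on the ribosomal list was 2.96 ± 0.546% in controls and 1.5 ± 0.0185% in overexpression libraries (SD, n = 4; exact permutation p = 0.0286, the smallest that 4 against 4 allow), and the share on mitochondrial genes was 3.42 ± 0.314% against 2.52 ± 0.109% (exact permutation p = 0.0286). Of the mitochondrial genome's own genes, 6 of 12 fell and 2 rose, including mt-Nd2 and mt-Cytb with log2 fold changes of -1.07 and -1.02 (-0.34 and -0.33 with the trend on gene length removed), and the list did not pass (camera, adjusted p = 0.129) except with GC correction (adjusted p = 0.0342, the lowest of 16 alternatives with camera, the highest being 0.565). The median of this list was -0.35, and it turned to 0.33 with the trend on gene length removed and was -0.76 with GC correction.

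**Figure D4:**
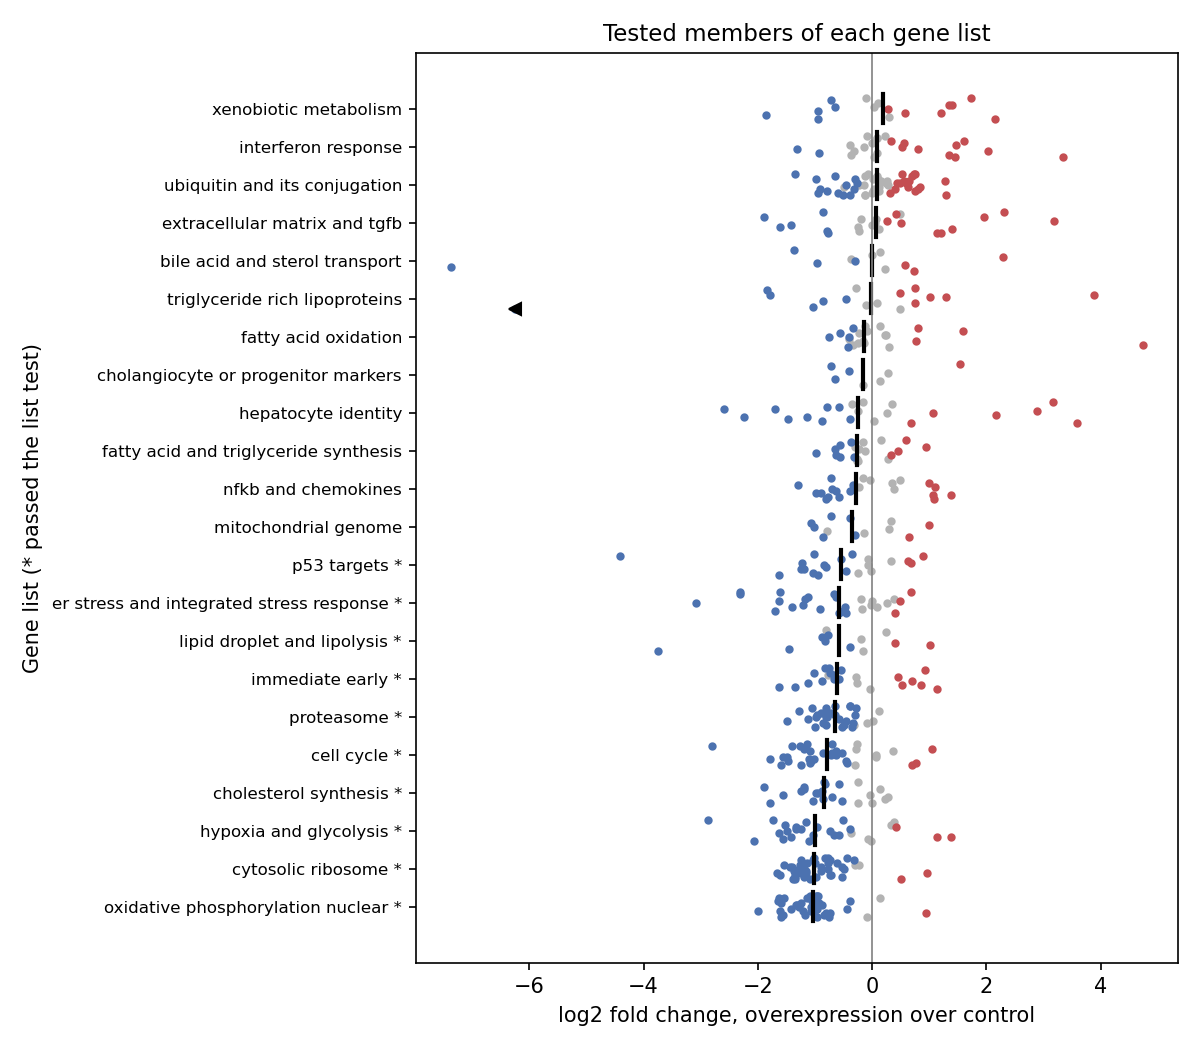
Log2 fold change of each tested member of the 22 tested gene lists (horizontal axis, overexpression over control; vertical axis, lists ordered by median; red higher and blue lower at an adjusted p below 0.05, grey neither; black bars, medians; black triangle, Scarb1 at its bound). All 10 lists that passed the list test have medians below 0.

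The lists of glycolysis, the cell cycle, the stress response and p53 targets were lower as well. Hypoxia and glycolysis genes fell for 20 of 28 members and rose for 3 (median log2 fold change -1; camera, adjusted p = 3.26e-06, and adjusted p = 0.283 with an estimated correlation). Ldha, which makes lactate, fell from 3504 ± 712 to 1048 ± 30.9 CPM (SD, n = 4), and Pgam1 and Pgk1 fell by 2.06 and 1.62 on the log2 scale. Cell cycle genes fell for 25 of 34 members and rose for 3 (median -0.79; camera, adjusted p = 1.53e-08, and adjusted p = 0.00997 with an estimated correlation). Ccne1, the cyclin of S-phase entry, fell from 13.1 ± 1.9 to 1.86 ± 0.155 CPM (SD, n = 4), and the replication genes Mcm5, Mcm3 and Pcna had log2 fold changes of -1.78, -1.59 and -1.48. Picked out after their values were seen, the members that rose were Mki67, Cenpe and Cenpf, genes of proliferating and dividing cells, with log2 fold changes of 0.70, 0.76 and 1.05. These values were not examined with the trend on gene length removed, so a part of that trend in them stays open. Stress response genes fell for 17 of 27 members and rose for 3 (median -0.57; camera, adjusted p = 8.73e-06, and adjusted p = 0.0878 with an estimated correlation). Mthfd2, Asns, Chac1 and Trib3, known targets of ATF4, had log2 fold changes of -2.31, -1.71, -3.08 and -2.31. Genes of protein folding and turnover in the endoplasmic reticulum, picked out after their values were seen, went both ways: Hspa5 and Pdia4 rose by 0.40 and 0.68, while Calr, Dnajb11, Manf, Sdf2l1 and Herpud1 had log2 fold changes of -0.47, -0.67, -0.57, -0.64 and -0.51. Targets of p53 fell for 13 of 21 members and rose for 3 (camera, adjusted p = 8.91e-04, and adjusted p = 0.056 with an estimated correlation), the members that rose being Mdm2, Sesn1 and Trp53inp1, also picked out after their values were seen, with Ddit4l at 19.5 ± 1.86 against 0.922 ± 0.272 CPM and Cdkn1a, a cell cycle inhibitor, at 365 ± 74.5 against 117 ± 9.06 CPM (SD, n = 4). Immediate early genes fell for 12 of 22 members and rose for 6 (camera, adjusted p = 0.0429, and adjusted p = 0.565 with an estimated correlation), Atf3 and Ier3 having log2 fold changes of -1.62 and -1.35, and the Ier3 log2 fold change being -0.63 with the trend on gene length removed. The immediate early call was lost without control library 4 and without overexpression library 2 or 4 (camera, adjusted p = 0.0744, 0.0571 and 0.0505, and 0.0311 to 0.565 over 16 alternatives), where its median was -0.51, -0.61 and -0.53 against -0.62 with all libraries. Over the same alternatives the adjusted p ran from 3.95e-07 to 0.283 for glycolysis, 1.87e-11 to 0.00997 for the cell cycle, 9.61e-07 to 0.0878 for the stress response and 4.73e-05 to 0.056 for p53 targets.

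Cholesterol synthesis was lower and showed no member that rose. It fell for 16 of 23 tested genes (median log2 fold change -0.84; camera, adjusted p = 1.21e-05, and adjusted p = 0.0474 with an estimated correlation). Insig1, a sterol sensor of the pathway, fell from 48.5 ± 8.04 to 13.1 ± 1.03 CPM and Cyp51, lanosterol demethylase, from 139 ± 18.3 to 47.5 ± 1.33 CPM (SD, n = 4), and Lss had a log2 fold change of -1.19. Genes of lipid droplets and lipolysis fell for 6 of 12 members and rose for 2 (camera, adjusted p = 0.0302, and adjusted p = 0.543 with an estimated correlation). Fabp5, a fatty acid carrier, fell from 80.1 ± 14.2 to 5.9 ± 0.955 CPM (SD, n = 4), and Hilpda, an inhibitor of lipolysis, had a log2 fold change of -1.46. The Hilpda log2 fold change was -0.73 with the trend on gene length removed. The lipid droplet call was lost without control library 2 or 4 and once the trend on gene length was removed (camera, adjusted p = 0.0598, 0.0913 and 0.0878, and 0.0169 to 0.543 over 16 alternatives), and the immediate early call also with that trend removed (adjusted p = 0.32). The lipid droplet medians in these 3 settings were -0.40, -0.43 and -0.20, and the immediate early median was -0.35 with the length trend removed. Both were lost with GC correction or chromosome centring, with medians of -0.51 and -0.68 for lipid droplets (-0.58 without them) and -0.32 and -0.53 for immediate early genes (-0.62 without them). The cholesterol synthesis call held in all 16 (adjusted p 9.61e-07 to 0.0474).

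Other lists held changes in both directions and did not pass the list test. Among hepatocyte identity genes, 6 of 21 rose and 9 fell (camera, adjusted p = 0.675, test direction down; median -0.25, mean 0.078). Alb, serum albumin, rose from 22.3 ± 3.85 to 267 ± 28.2 CPM, while Ttr, transthyretin, fell from 1321 ± 239 to 279 ± 24.2 CPM (SD, n = 4). Of fatty acid oxidation genes, 4 of 21 rose and 5 fell (camera, adjusted p = 0.596, test direction up; median -0.14, mean 0.22), with Vnn1 rising from 29.7 ± 4.67 to 89.2 ± 5.13 CPM (SD, n = 4). Fatty acid and triglyceride synthesis had 4 of 20 higher and 7 lower (camera, adjusted p = 0.481), with Fads2 at a log2 fold change of -0.98 and Mlxipl at 0.94. Bile acid and sterol transport had 3 of 11 higher and 4 lower (camera, adjusted p = 0.336, test direction down; median 0.00466, mean -0.58), Nr1h3, a sterol-sensing receptor, having a log2 fold change of -1.36. Xenobiotic metabolism had 7 of 16 higher and 5 lower (camera, adjusted p = 0.336), including Ahr at 2.15 and Gclc at 1.39. Interferon response had 10 of 23 higher and 2 lower (camera, adjusted p = 0.0851), with Ifit1 and Ifih1, a sensor of double-stranded RNA, at 3.34 and 2.02. Both of the last lists passed once the trend on gene length was removed (camera, adjusted p = 0.0175 and 0.00581, the lowest of 16 alternatives with camera, the highest being 0.613 and 0.283), and the interferon list also without control library 1 or overexpression library 1 (camera, adjusted p = 0.0339 and 0.0179). Ubiquitin and its conjugation had 17 of 49 higher and 13 lower (camera, adjusted p = 0.675), with Cbl at 1.30 (the Cbl log2 fold change was 0.72 with the trend on gene length removed) and Ube2g2 at -1.34. NF-kB and chemokine genes had 5 of 22 higher and 11 lower (camera, adjusted p = 0.562), with Nfkbiz at 1.08 and Cxcl2 at 1.09. Matrix and TGF-beta genes had 9 of 23 higher and 6 lower (camera, adjusted p = 0.547), with Col12a1 at 3.18 and Col6a1 at 2.30.

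Markers of other cell types moved apart. Cholangiocyte or progenitor markers rose for 1 of 7 tested members and fell for 3 (camera, adjusted p = 0.983, test direction down; median -0.16, mean 0.000649): Spp1 rose from 943 ± 209 to 2731 ± 114 CPM and Sox9 fell from 91.3 ± 9.52 to 57.9 ± 0.91 CPM (SD, n = 4). The macrophage, endothelial, stellate and erythroid lists had 4, 4, 2 and 2 tested members, too few for the list test. Csf1r and Cd14 fell by 1.40 and 0.66 on the log2 scale, and the Cd14 log2 fold change was -0.16 once the trend on gene length was removed (edgeR, adjusted p = 0.193, and 5.94e-08 to 0.193 over 19 alternatives). Cdh5 rose from 7 to 71 counts and Eng fell from 180 to 53. Des and Col1a1 rose by 1.51 and 1.21, and Slc4a1 fell by 2.60. Counts of members adjusted over the list alone equalled those above except for 1 more lower gene in the lipoprotein, lipid droplet and proteasome lists (7, 7 and 28), 1 more higher xenobiotic gene (8), and 1 fewer lower gene in the ubiquitin and cholangiocyte lists (12 and 2).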

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

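The length, GC content and chromosome corrections, and the tests of admixture, swap, antisense reads and neighbourhood, were chosen only after the data had been seen, as was the set of genes on which the trends of control library 3 were judged. A library far from the other 3 of its group was looked for in 192 groups of values, and 14 stood out; chance flags about 1 in 20 groups. In 4 of them the library was control 3: Hilpda at 19 CPM, Cbl at 68.4 CPM and Ifih1 at 5.56 CPM, with Slc22a8 at 0.125 CPM resting on 2 counts. Values resting on 1 to 3 counts were also Lpl at 0.0745 CPM in overexpression library 4, Gpnmb at 0.0551 CPM in overexpression library 2, Dync2li1 at 0.0872 CPM in overexpression library 3, Speer4f1 at 0.0768 CPM in control library 4 and Fmod at 0.161 CPM in control library 2. The others were Apoa1 at 1.54 CPM in overexpression library 2, Cdkn1a at 131 CPM and Pgam1 at 114 CPM in overexpression library 1, Sox9 at 105.5 CPM in control library 4, and the share of counts on the ribosomal list, 1.47% in overexpression library 4.

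Most tested genes differed between the groups. Of the 35 splits into 4 and 4 libraries, only the real split, 1 of 35, gave as many as 7417 called genes. The highest of the others gave 0 in edgeR's test. At an unadjusted p under 0.05 the real split gave 7791 and the others at most 4176. Every other split mixed the groups, which raised its spread, so its 0 calls were to be foreseen. The splits argue against a chance division of these 8 libraries, but cannot exclude a chance difference between cultures. The labels do not say whether the libraries of a group came from separate cultures. The log2 fold changes rose with gene length (Spearman 0.411 across genes, which are not independent replicates) and fell with GC content (-0.336). With either trend removed 6979 and 8226 genes were called, with both removed 7890, and with each chromosome centred 7478. These totals include genes not called before. Of the 7417 calls, 5757 were also called with the length trend removed, 65 of them with the opposite sign. With both removed 5850 were also called, 226 of them with the opposite sign. The GC correction kept 6523 and chromosome centring 6925. Most calls were thus kept each time. However, each corrected fit called most of the 11520 tested genes, so much of this overlap would arise by chance. The numbers still called after each correction argue against any of these trends, as removed here, as the whole cause. The overexpression itself may account for the rest, but a difference in vector, culture or library preparation that runs along the groups was not tested. The labels give no batch, and the sample titles name a vector for the controls only.

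Control library 3 lay apart from the other controls, toward the overexpression libraries. Over 2366 genes changed at least 2-fold it lay at a median of 33.3% of the way to them. That median was 22% over the 1327 higher genes and 48.1% over the 1039 lower genes. Over 8 higher genes nearly confined to the overexpression libraries it was 0.642%, which argues against an admixture of overexpression cells. The overexpression libraries correlated at 0.9888 or more with each other, so none was out of place as a swap would need. Its deviations correlated across genes at 0.0358 with gene length and -0.456 with GC content, against -0.457 to -0.408 and 0.293 to 0.594 in the other controls and 0.362 to 0.416 and -0.372 to -0.283 in the overexpression libraries, so its GC trend had their sign and lay beyond theirs. Over the 2366 genes, removing the length trend alone left a median of 26.5% (95% bootstrap interval over genes 24.6 to 28.3). Removing the GC trend alone left 21.7% (20.3 to 22.9). These values argue against either trend alone as the whole cause, narrowly so for GC against a bound of 20%. Over the 1783 genes called after the length correction the median was 20.9% (18.8 to 22.7). That interval spans the bound and leaves length undecided there. The intervals resample genes, not libraries, and describe only control library 3. Removing both left 10.4% (8.82 to 12), so both trends together may account for most of the difference and stay open, and no biological explanation was tested.

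Apoa5 had more reads in the overexpression libraries, and antisense reads from Gm47544 counted on Apoa5 are a candidate explanation. The 196 overexpression counts cannot be told apart by origin, because gene counts hold neither strand nor position. An activation reaching the genes at higher coordinates is argued against by Zpr1, the nearest tested gene, whose log2 fold change was -0.079 (SE 0.0997). Bud13, on the same side, had -0.35 (SE 0.141). At lower coordinates Apoa1 had 0.49 (SE 0.48) and Sik3 0.26 (SE 0.12), not called in the main test. Apoa4 had 0 and 3 counts, so an activation on that side stays open. A rise of Apoa5 transcripts themselves stays open.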

How the results depend on the processing

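The length, GC and chromosome corrections were chosen only after the data had been seen; the other alternatives were fixed before. Leaving out each library gave 6659 to 9001 changed genes, the highest without control replicate 3, and no other test, scaling, filter, block or correction moved the numbers of changed, higher or lower genes by over 1.5 times; requiring a 2-fold change as well left 2366. The replicate numbers did not pair the samples. Same-numbered libraries had correlations of 0.0227, -0.011, -0.0773 and -0.119 between their deviations, and no library correlated best with its own number. With the replicate block 7129 genes changed. Of 10 lists called, 2 held with an estimated correlation, while fry, which does not compare a list with other genes, called 17; leaving out each library gave 8 to 11. The Gm47544 log2 fold change has no value here. The Apoc3 log2 fold change ran from -0.26 to 0.60 over the left-out libraries and was -0.20 with limma-voom and -0.073 with chromosome centring; 13 counts in each group set that limit. Of 1824 named-gene values, 1798 kept direction and side of the threshold, 10 lost the call, 6 gained it and 10 reversed. The Zpr1 log2 fold change was 0.048 with library totals, 0.039 with the length and 0.028 with the GC correction, the Sik3 log2 fold change was -0.18 with the length correction and at its highest, 0.53 and called, with the GC correction, and the Apoe log2 fold change ran from -0.096 to 0.20 over the left-out libraries. Of 374 list values 320 kept both, 19 lost the call, 12 gained it and 23 reversed, all in lists not called. The reversed medians were, for triglyceride-rich lipoproteins, -0.101 to 0.067 over the left-out libraries, 0.12 with library totals, 0.092 with the length correction, 0.061 with the GC correction and 0.14 with chromosome centring; for bile acid and sterol transport -0.081 to 0.0445 over the left-out libraries, -0.00537 with RLE factors, -0.14 with the stricter filter, -0.20 with the length correction, -0.055 with the GC correction and -0.16 with chromosome centring; for fatty acid oxidation 0.053 and 0.032 with the length and GC corrections; with the length correction also -0.0415 for matrix genes, 0.33 for the mitochondrial genome and 0.0695 for cholangiocyte markers; and with the GC correction -0.18 for ubiquitin and 0.035 for hepatocyte identity. The cause was not tested.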

Other observations

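Families grouped by symbol after the data had been seen showed further sets that moved together; 20 families were tested in both directions by Fisher's exact test on genes changed at least 2-fold, with Benjamini-Hochberg adjustment over 40 tests. All 9 tested Ugt genes, which conjugate drugs and steroids with glucuronic acid, rose at least 2-fold (adjusted p = 4.65e-08), as did 21 of 37 Cyp genes, with 2 lower (adjusted p = 1.39e-09); with library totals alone or with the length trend removed these were 9 and 9, and 25 and 26. Ugt2b34 rose from 75.5 to 489 CPM and Cyp2d26 from 40.3 to 341 CPM, although reads of such families may be shared between relatives. With the length correction 6979 genes were called in all. Of all 11520 genes tested in the main fit, 1327 rose and 1039 fell at least 2-fold. Collagen genes rose for 10 of 17 (adjusted p = 2.88e-05) and zinc finger genes named Zfp for 62 of 306 (adjusted p = 3.59e-05; 85 with library totals and 55 with the length trend removed). Genes of the mitochondrial ribosome fell at least 2-fold for 27 of 75 (adjusted p = 2.35e-09), 20 with library totals and 12 with the length trend removed. Histone genes fell for 9 of 16 (adjusted p = 2.44e-05; 4 with the length trend removed) and S100 genes for 6 of 11 (adjusted p = 8.24e-04; 3 with the length trend removed). Timm and Tomm genes fell for 9 of 22 (adjusted p = 3.67e-04; 4 with the length trend removed) and Trim genes rose for 10 of 39 (adjusted p = 0.0441). Serpin genes went both ways, 8 of 23 lower (adjusted p = 0.00271) and 5 higher, or 5 lower and 6 higher with the length trend removed. Families, examples and the comparison of chromosomes were picked after their values were seen. The Fisher tests treat genes as independent, which members of a family need not be, so their p-values do not measure the spread between libraries. They were not recomputed with library totals or with the length trend removed, and the families were not examined with the GC trend removed.

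Chromosomes differed in their median log2 fold change, with a range of 0.53 against at most 0.329 in 1000 shuffles of the genes (permutation p = 9.99e-04, the smallest they can give). After the GC correction the range was 0.319, against at most 0.254 in 1000 shuffles of the corrected values (permutation p = 9.99e-04). The shuffles treat genes as independent, which neighbours need not be, so these p-values do not measure the spread between libraries. The range was not examined with the length trend removed. Chromosomes 12 and 9 moved from 0.332 and 0.255 to 0.227 and 0.208, while chromosomes 18 and 7 moved from 0.24 and -0.198 to 0.052 and -0.0432.

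A hypothesis was that segments of the genome lost from 1 culture explain genes absent from a group. There were 10 genes at or under 0.2 CPM in every library of a group and over 2 CPM in every library of the other, 7 absent in the overexpression libraries and 3 in the controls. They held 1 pair within 5 genes of each other, Evc and Evc2, a number that shuffled positions seldom reached (permutation p = 0.0181, at most 2 pairs in a shuffle), as segments of the genome lost from one culture would predict. This rests on 1 pair of adjacent genes, which may equally share their regulation. The nearest expressed genes on both sides of the pair, Wfs1 and Stx18, had log2 fold changes of -0.057 and -0.40. Among the nearest expressed genes beside the other 8, both neighbours of Speer4f1 rose (Cacna2d1 1.42, Sema3c 1.38) and both of Fam57b fell (Aldoa -1.48, Ino80e -0.81). Those of Fmod went both ways (Atp2b4 2.88, Btg2 -1.01), as did those of Gpnmb (Aoc1 1.65, Malsu1 -0.69), and those of Dync2li1 and Scarb1 lay between 0.0072 and 0.38. Beside Ces3a, Ces2g rose by 0.74 and Cbfb had 0.042, and beside S100a8, S100a7a and Sprr2g had -0.39 and -0.66. All of these neighbours were expressed in both groups.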
